A study of Homo sapiens with 16 samples.

How the data were processed

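RNA sequencing was reported for 16 libraries of MCF-7, an estrogen receptor positive luminal breast cancer cell line. There were 4 groups of 4 replicates: Control, LCL-161+TRAIL, zVAD and LCL-161+TRAIL+zVAD. Per the labels' protocols, LCL-161 was given at 10 µM, TRAIL at 100 ng/ml and zVAD-fmk at 20 µM. The duration of treatment was not given. RNA was extracted with a column kit and made into stranded mRNA libraries, per the labels' protocols. The submitters' processing notes list bcl2fastq 2.18.0.12, HISAT2 and StringTie (no version given for the last pair) and the genome build GRCh38. The gene annotation was not stated. The values deposited by the authors are TPM, in a table of 58051 gene rows with a column per library, and each column sums to 1e+06. TPM keep no read depth, so the depth of each library is unknown and no counting interval was computed. The precision of each value is given by the spread between replicates.

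Genes were named as in the deposited table, which held 56305 distinct names. The 1995 rows whose name occurred more than once were kept as separate rows and were not eligible to be named, and 16 rows had names turned into dates. Rows were matched to GENCODE v29 (GRCh38) for position, class and GC content. In all, 36032 rows matched by name, 27 by an older symbol and 623 by a RefSeq synonym, while 21369 matched no single gene. The RefSeq synonyms were added after a check of gene overlaps had been seen with fewer matches, which the closing section describes. GC content was that of the longest annotated transcript and was available for 13080 of the tested genes (87.6%).

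The analysis was run in R 4.3.3 with limma 3.58.1. Values were transformed as log2(TPM + 1), and the 14938 genes with a mean of at least 1 TPM over the 16 libraries were tested. A linear model with a coefficient per group was fitted to all libraries (12 residual degrees of freedom) with moderated variances and a mean-variance trend. Comparisons were LCL-161+TRAIL vs Control, zVAD vs Control, LCL-161+TRAIL+zVAD vs zVAD, LCL-161+TRAIL+zVAD vs LCL-161+TRAIL and LCL-161+TRAIL+zVAD vs Control. The interaction was the LCL-161+TRAIL effect under zVAD minus that without zVAD. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Log2 changes on this scale understate the ratio of TPM for genes with low values. No ratio is given against a group in which a gene was listed at 0.

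The groups, tests, gene lists and rule for naming genes were fixed before the data were examined, with a branch for counts that did not apply. In LCL-161+TRAIL vs Control, zVAD vs Control and LCL-161+TRAIL+zVAD vs zVAD, the rule took the 10 highest and 10 lowest log2 changes among genes past the threshold with a gene symbol, a mean of at least 2 TPM in the higher group and no overlap between the values of the 2 groups. It took 5 and 5 in the other comparisons, without the overlap condition for the interaction. In every comparison it added up to 4 members of each list past the threshold, the 2 largest increases and the 2 largest decreases. BIRC2, BIRC3, XIAP, TNFRSF10A, TNFRSF10B, CASP3, CASP8, CFLAR, RIPK1, RIPK3, MLKL, CXCL8, NFKB2, TNFAIP3 and ESR1 were named whatever their change. Other members of the lists that are named were chosen after their values were seen, and each is marked so.

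The 20 biological lists covered NF-kB targets, cytokines and chemokines, interferon-stimulated genes, MHC class I antigen presentation, the death receptor and IAP pathway, the BCL2 family, p53 targets, the unfolded protein and integrated stress responses, heat shock, estrogen-induced genes, luminal identity, mesenchymal and invasion genes, S phase, G2 and M phase, immediate early and AP-1 genes, NRF2 targets, sterol and fatty acid synthesis, hypoxia and glycolysis, autophagy and lysosome, and proteasome subunits. They were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison. Members below the filter were not tested, which left 12 of 30 cytokines and chemokines, 8 of 17 MHC class I genes and 11 of 20 mesenchymal and invasion genes. A repeated name was read from its first row alone. The filter used the mean over all libraries, so a gene silent in Control was tested only where a treatment raised it. This favors calls in that direction. Ribosomal protein genes, mitochondrially encoded genes, reference genes and markers of fibroblasts, leukocytes, endothelial and basal cells were described and not tested. RNA classes (small nuclear RNA, small nucleolar RNA, microRNA, small Cajal body RNA, replication-dependent histones and mitochondrial transcripts) were taken from the annotation and gene names and were added after the data were seen.

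The gene test was checked on simulated data drawn from the means and spreads of the 14938 genes. For LCL-161+TRAIL vs Control it recovered 16% of 50 genes planted with a log2 change of 0.5, 82% of 50 at 1, 96% of 50 at 2 and 66% of 50 at -1, and 6.47% of all calls were false. For the interaction it recovered 4% of 50 genes at -0.5, 50% of 100 at -1 and 82% of 50 at -2. For zVAD vs Control it recovered 22% of 50 genes at 0.5, 70% of 100 at 1 and 92% of 50 at 2, and it made 0 calls where nothing was planted. The simulated noise was drawn once per setting and was independent between genes and libraries, without GC trends or pairing. These rates therefore do not give the error rate on the real libraries.

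Alternatives set before the data were seen were limma without the trend, quantile normalization, no filter, a mean of at least 5 TPM, a pseudocount of 0.1, an adjusted p below 0.01, fits on only the libraries of the groups compared, replicate number as a block, and leaving out each library in turn. For the lists they were an estimated inter-gene correlation and fry. Alternatives chosen after seeing the data removed the GC trend of each library (a lowess curve with a span of 0.3 through the deviation of each gene from its mean), removed mitochondrial genes and rescaled the rest, left out genes whose values fell into 2 levels within a group, or left out the 2 libraries with the most negative GC trends. A gene had 2 levels when the widest gap between its sorted log2 values was at least 1, at least 3 libraries lay on each side and a group had libraries on both sides. The labels number the replicates 1 to 4 in every group and do not say whether a number marks shared handling. After group means were removed, all 4 pairs of the same number correlated above 0.1 between LCL-161+TRAIL and Control (0.130 to 0.430, and 0.105 to 0.213 with GC trends removed), so the numbers were taken to pair the samples in that comparison, from the data and not from the labels. In no other comparison did all 4 pairs, though 3 did between LCL-161+TRAIL+zVAD and zVAD. Fits with the block on the 8 paired libraries alone, and with the block after removal of GC trends, were added for that comparison. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.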

Results

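The data were transcript abundances in MCF-7 breast cancer cells left untreated (Control) or given LCL-161 and TRAIL together, the caspase inhibitor zVAD, or all 3 agents, with 4 biological replicates per group. LCL-161 is a Smac mimetic that antagonises inhibitor of apoptosis (IAP) proteins, and TRAIL is a ligand of death receptors. Between 14474 and 15178 gene rows reached 1 TPM in a library. Correlations of log2 values within groups ranged from 0.941 to 0.974. Of the total TPM, mitochondrially encoded transcripts took 18.1 ± 2.28% in Control (mean ± SD, n = 4), 14.7 ± 1.68% with LCL-161+TRAIL, 23.3 ± 3.23% with zVAD and 20.9 ± 2.38% with all 3 agents. Replicates of a group also differed in the relation of expression to GC content, with slopes from -0.34 (Control 3) to 0.21 (LCL-161+TRAIL 2) log2 units per 10 percentage points of GC. The second principal component, 18.2% of the variance, had gene loadings correlated with GC content across genes (r = 0.641), where genes are not independent replicates. Values below are TPM as mean ± SD of 4 replicates and log2 changes as estimate ± SE, with limma's adjusted p.

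The first comparison was of LCL-161+TRAIL with Control. NF-kB target genes had the highest median rise of the 20 lists, led by TNFAIP3, which encodes the feedback inhibitor A20 (chromosome 6, 137867188 to 137883312 on GRCh38). TNFAIP3 stood at 0.299 ± 0.0834 TPM in Control and 47.5 ± 15.1 with LCL-161+TRAIL, a log2 change of 5.18 ± 0.17 (adjusted p = 1.22e-10). The adhesion molecule gene ICAM1 (chromosome 19, 10270835 to 10286615) went from 1.38 ± 0.236 to 84.5 ± 37.2 TPM, and NFKBIA, which encodes the NF-kB inhibitor IκBα, from 75.4 ± 2.51 to 1300.0 ± 372 TPM. NFKB2 changed by 2.73 ± 0.28 and the IAP gene BIRC3 by 2.25 ± 0.16, the latter from 0.0469 TPM. Of 21 NF-kB targets tested, 17 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 change of 2.25 (adjusted p = 9.88e-27).

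Inflammatory mediators, interferon-stimulated genes and immediate early genes rose with them. CCL20, ICAM4, IFNL2 and CXCL3 were listed at 0 in all Control libraries. With LCL-161+TRAIL they reached 18.6 ± 4.20, 24.8 ± 10.7, 17.0 ± 9.29 and 5.62 ± 1.00 TPM, and CXCL8 reached 9.69 ± 2.38 TPM (adjusted p = 2.49e-09). Of the 30 cytokines and chemokines listed, 12 were tested and 8 of these were higher (8 higher and 1 lower adjusted over the list alone). CCL20, CXCL3 and CXCL8, at or near 0 in Control, reached the filter only through their values with LCL-161+TRAIL. This selection favors a higher share and a smaller adjusted p for the list. Of 34 interferon-stimulated genes, 28 rose (30 adjusted over the list alone), among them IFIT1, from 3.52 ± 1.71 to 103 ± 22.7 TPM (log2 change 4.57 ± 0.38), and IFIT2 (3.56 ± 0.29). Of 23 immediate early and AP-1 genes, 17 rose (19 adjusted over the list alone), including the transcription factor genes JUN (3.49 ± 0.22) and JUNB (3.51 ± 0.38). The small GTPase gene RASD1 rose by 3.99 ± 0.29. Median log2 changes of the cytokine, interferon and immediate early lists were 1.19, 1.90 and 1.48 (adjusted p = 8.86e-11, 6.37e-38 and 1.40e-22).

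Stress and cell death genes rose in smaller shares of their lists. In the unfolded protein and integrated stress response list 9 of 21 members rose (9 adjusted over the list alone, adjusted p = 1.54e-08), with PPP1R15A, a phosphatase subunit that reverses eIF2α phosphorylation, at 3.95 ± 0.24 and ATF3 at 2.95 ± 0.25. Among p53 targets 9 of 24 rose (13 adjusted over the list alone), including GDF15 (3.04 ± 0.26) and BBC3 (3.11 ± 0.44), which encodes the BH3-only protein PUMA and also stands in the BCL2 family list. In the BCL2 family 3 of 14 rose (6 adjusted over the list alone), BBC3, PMAIP1, the gene of NOXA (1.74 ± 0.16), and MCL1 (0.66), the last chosen after its values were seen. Among NRF2 targets 6 of 18 rose (9 higher and 1 lower adjusted over the list alone), led by the heme oxygenase gene HMOX1 (2.70 ± 0.23) and the cystine transporter gene SLC7A11 (1.53 ± 0.28). The death receptor and IAP list had 6 of 26 members higher (8 adjusted over the list alone), including CYLD (1.45 ± 0.21) and the TRAIL receptor gene TNFRSF10B (0.90 ± 0.17). BIRC2, XIAP, TNFRSF10A, CASP3, CASP8, CFLAR, RIPK1, MLKL and ESR1 did not pass the test, with log2 changes of 0.23, 0.17, 0.42, 0.27, -0.04, 0.44, 0.32, 0.30 and -0.51 respectively. With the replicate number as a block, TNFRSF10A (adjusted p = 0.0441), CFLAR (0.0276) and RIPK1 (0.0336) passed as higher. With the block on the 8 libraries of this comparison alone they did not (0.0502, 0.0666 and 0.0795), and ESR1 passed as lower (0.0293). ESR1 stood at 20.6 TPM in zVAD 1, which enters the spread of the main fit, and at 65.9 to 87.8 TPM in the other zVAD libraries. With GC trends removed, TNFRSF10A, CFLAR, RIPK1, BIRC2 and CASP3 passed as higher, with the block (0.0212, 0.0145, 0.00987, 0.0305 and 0.0387) and without it, so these calls depend on the fit. RIPK3, a kinase needed for necroptosis, was listed at 0 in every group. The calls for the p53, BCL2, NRF2 and death receptor lists were lost with an estimated correlation (adjusted p = 0.0648, 0.0648, 0.102 and 0.0648), and those for NF-kB targets, cytokines, interferon-stimulated genes, immediate early genes and the stress response list were not (adjusted p = 0.0158, 0.0171, 0.0223, 0.0112 and 0.0444).

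Each of the other lists had at most 3 members past the threshold. Of 11 mesenchymal and invasion genes 3 rose (6 higher and 1 lower adjusted over the list alone, adjusted p = 2.20e-04, and 0.0388 with an estimated correlation), the transcription factor genes SNAI1 (3.25 ± 0.25) and SNAI2 (0.90 ± 0.12) and the laminin gene LAMC2 (0.58). LAMC2 here, and IDI1 and WIPI1 below, were chosen after their values were seen. The inducible chaperone gene HSPA6 rose from 0.519 ± 0.171 to 24.9 ± 12.6 TPM. In the heat shock list, which does not hold HSPA6, HSPA1B (1.19 ± 0.20) and DNAJB1 (1.00 ± 0.13) rose, 2 of 14 members (4 adjusted over the list alone, adjusted p for the list 0.0695, and 0.0287 with the replicate number as a block). The sterol list had 3 of 20 higher (6 adjusted over the list alone), LDLR (0.59 ± 0.14), INSIG1 (0.46 ± 0.12) and IDI1 (0.43). The autophagy and lysosome list had 3 of 23 higher (5 adjusted over the list alone), GABARAPL1 (1.90 ± 0.31), SQSTM1 (1.67 ± 0.34) and WIPI1 (0.58). The MHC class I list, of which 8 of 17 members were tested, had 2 higher (2 adjusted over the list alone), B2M (0.67 ± 0.16) and PSME2 (0.44 ± 0.11). The adjusted p of these lists, 0.00110, 0.0158 and 0.0312, became 0.0648, 0.311 and 0.202 with an estimated correlation. In the G2 and M phase list CDK1 (-0.51 ± 0.13) and UBE2C (-0.41 ± 0.10) fell, 2 of 22 (2 adjusted over the list alone). In the S phase list 1 of 21 fell, GINS2 (-0.34 ± 0.10) (0 adjusted over the list alone). The adjusted p of both cell cycle lists, 0.00110 and 0.0419, became 0.168 and 0.311 with an estimated correlation. The luminal list had 1 of 18 higher, ELF3 (1.19 ± 0.23), and the hypoxia list 2 of 18, VEGFA (1.40 ± 0.33) and ANKRD37 (0.75 ± 0.16). The estrogen-induced list had 1 of 23 lower, RET (-0.37 ± 0.11), and the proteasome list 0 of 26 higher and 0 lower. These 4 lists did not pass the list test (adjusted p = 0.823, 0.205, 0.987 and 0.871), and the medians of the last pair changed sign between scalings.

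The largest decreases included METTL7A, from 13.5 ± 2.48 to 3.57 ± 1.41 TPM (log2 change -1.71 ± 0.23), MYZAP (-1.83 ± 0.35), the kinetochore gene SPC24 (-1.38 ± 0.32), PRR15L (-0.97 ± 0.17) and RAB5B (-2.36 ± 0.51), whose values fell into 2 separate levels within groups. CDK2AP1 (-1.31 ± 0.30), the dynein assembly gene DNAAF3 (-1.13 ± 0.33), SEMA3D (-1.0 ± 0.24), the kinase gene MAP2K6 (-1.0 ± 0.26) and MIR503HG (-0.96 ± 0.24) fell as well. With the replicate number as a block the adjusted p of DNAAF3 was 0.0721. In all, 765 genes rose and 388 fell. The number was 566 without LCL-161+TRAIL 4, 717 without Control 1, 507 when only these 8 libraries were fitted (1269 with the replicate number as a block), 1613 with the block on all libraries, 1944 with GC trends removed and 2434 with both. The share of changed genes that rose, 66.3%, was 54.4% with mitochondrial genes removed (701 higher, 588 lower) and 55.5% after quantile normalization (728 higher, 584 lower). Of the genes named for this comparison, the calls of CDK1, UBE2C, RET, SPC24, VEGFA, ANKRD37, GINS2, LDLR, INSIG1, B2M, PSME2, CDK2AP1, DNAAF3, SEMA3D, MAP2K6 and MIR503HG were lost in at least 1 alternative (highest adjusted p 0.124, 0.0814, 0.166, 0.103, 0.0630, 0.0566, 0.156, 0.0903, 0.105, 0.0877, 0.0921, 0.0831, 0.155, 0.0673, 0.111 and 0.0907 in that order).

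**Figure D1:**
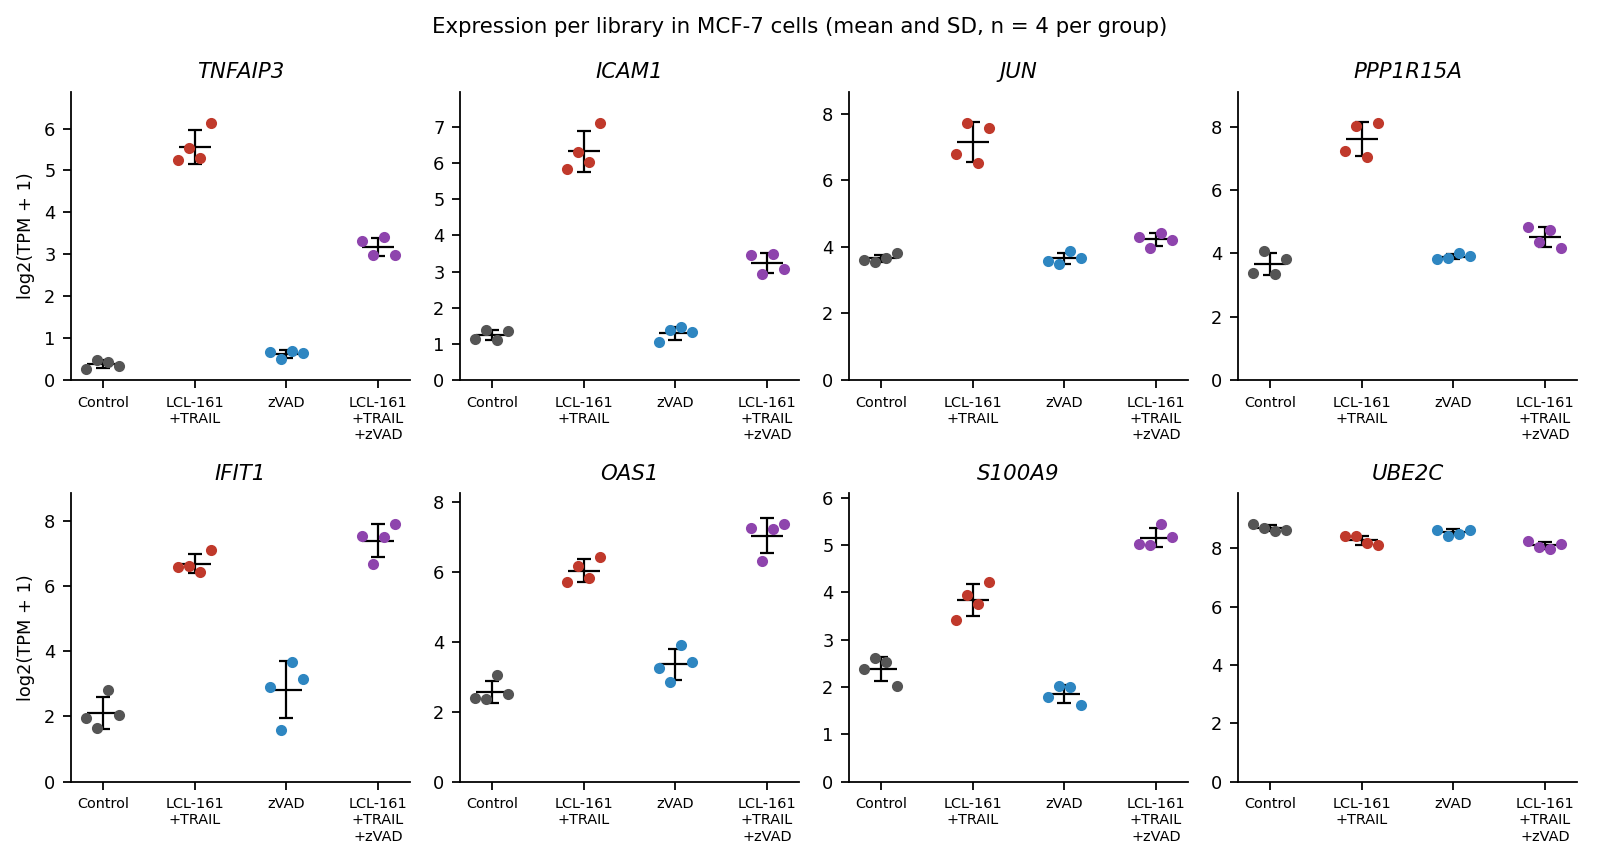
Expression of 8 genes, a panel per gene, with the treatment group on the x axis and log2(TPM + 1) on the y axis; each point is a library, and bars give the mean and SD of 4 replicates. TNFAIP3, ICAM1, JUN and PPP1R15A were highest with LCL-161+TRAIL (TNFAIP3 47.5 TPM) and lower when zVAD was added (8.11 TPM), while the means of IFIT1, OAS1 and S100A9 were highest with all 3 agents.

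Several RNA classes were also read between these groups, by counts and medians, and no class was tested as a set. Over all 14938 tested genes, 765 were higher and 388 lower (median 0.01). Of 53 small nuclear RNA genes tested, 31 were higher and 0 lower with LCL-161+TRAIL than in Control, with a median log2 change of 1.00. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had 10 of 55 higher and 0 lower (median 0.38). The 2 mitochondrial ribosomal RNA genes were both higher (median 0.67), while 8 of 13 mitochondrial protein-coding genes were lower (median -0.53, and -0.34 after quantile normalization), among them MT-CO2, from 32417 ± 4184 to 19536 ± 3003 TPM, and MT-ND6 (-0.75 ± 0.19, highest adjusted p in other settings 0.115). MicroRNA genes had 3 of 55 higher (MIR616, MIR3189 and MIR6807, median 0.09), small Cajal body RNA genes 1 of 3 higher (SCARNA13, median 0.11) and small nucleolar RNA genes 11 of 70 higher and 1 lower (SNORD50B, median 0.51), with these named genes chosen after their values were seen. Whether the values of such short entries, microRNA above all, hold reads of overlapping genes was not tested. Among ribosomal protein genes 1 of 26, RPL11 (0.28 ± 0.07), was higher, a call lost in other settings (highest adjusted p 0.146), and 0 of 11 reference genes passed the test.

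**Figure D2:**
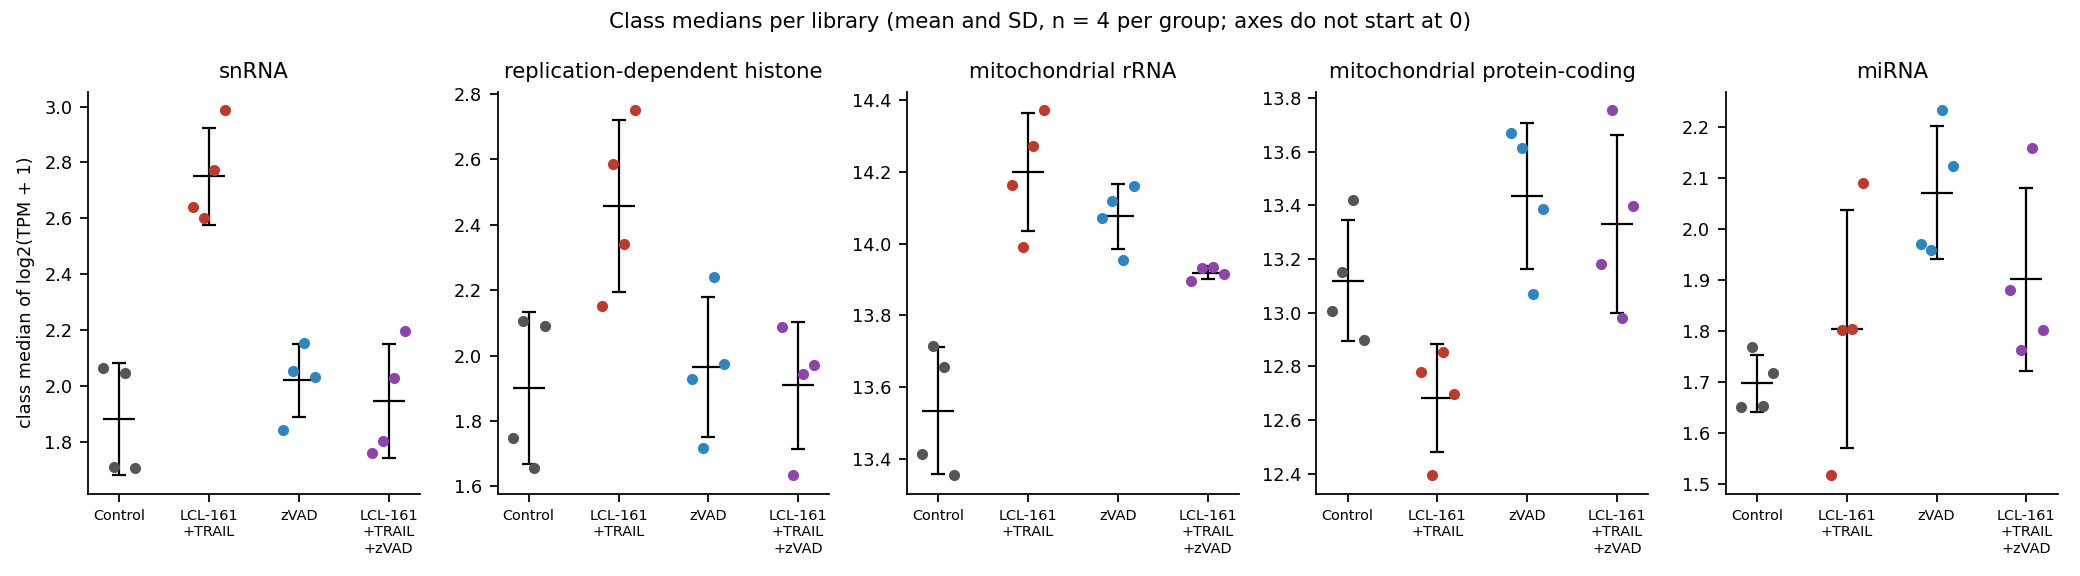
Class medians of log2(TPM + 1) per library (y axis, with a separate scale per panel that does not start at 0) for 5 RNA classes, by treatment group (x axis), with bars for the mean and SD of 4 replicates. Small nuclear RNA medians were 2.60 to 2.99 in the LCL-161+TRAIL libraries and 1.71 to 2.06 in Control.

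Treatment with zVAD alone was compared with Control as the background for the combination. No gene passed the test: limma with and without the trend called 0 genes, the smallest adjusted p was 0.50, and 824 genes had an unadjusted p below 0.05 where 747 are expected by chance. TNFAIP3 stood at 0.543 ± 0.0948 TPM with zVAD and CXCL8 at 0.0154 ± 0.0308 TPM, with log2 changes of 0.25 ± 0.17 and -0.02 ± 0.16. Those of BIRC2, BIRC3, XIAP, TNFRSF10A, TNFRSF10B, CASP3, CASP8, CFLAR, RIPK1, MLKL, NFKB2 and ESR1 lay between -0.61 (XIAP) and 0.14 (TNFRSF10B). The 26 proteasome subunit genes had a median log2 change of -0.27, with 0 past the threshold over all genes and 7 lower adjusted over the list alone (adjusted p = 7.04e-12 for the list, 0.0641 with an estimated correlation). The lists of interferon-stimulated genes (median 0.21), heat shock (-0.22), estrogen-induced genes (-0.13), G2 and M phase (-0.16), S phase (-0.10) and hypoxia (-0.16) passed the list test with 0 members past the threshold, over all genes or over the list alone. None of these 7 calls held with an estimated correlation (adjusted p of the last 6 from 0.553 to 0.775). The remaining 13 lists did not pass (adjusted p from 0.377 to 0.994). The 13 mitochondrial protein-coding genes had a median log2 change of 0.34 (0 after quantile normalization), with 0 past the threshold over all genes and 11 higher adjusted over the list alone. The 2 mitochondrial ribosomal RNA genes had a median of 0.54, also with 0 past the threshold.

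The effect of LCL-161+TRAIL when caspases were inhibited was read from LCL-161+TRAIL+zVAD against zVAD. Interferon-stimulated genes had the highest list median. IFIT1 (chromosome 10, 89392546 to 89406486) went from 6.98 ± 3.97 to 174 ± 55.9 TPM (log2 change 4.57 ± 0.38, adjusted p = 3.83e-06), the antiviral synthetase genes OAS1 and OAS2 changed by 3.68 ± 0.26 and 3.86 ± 0.31, IFIT3 by 3.63 ± 0.32, MX1 by 2.98 ± 0.25, PARP9 by 2.94 ± 0.22, the RNA sensor gene DDX58 by 3.02 ± 0.22 and IFI6, whose values fell into 2 levels within groups, by 3.15 ± 0.64. Of the 34 members 29 rose (34 adjusted over the list alone, median 2.54, adjusted p = 1.65e-89, and 0.00318 with an estimated correlation). S100A8 and S100A9, which encode the subunits of calprotectin, rose from 0.290 ± 0.209 to 20.9 ± 6.06 TPM and from 2.65 ± 0.464 to 34.98 ± 5.29 TPM (log2 changes 4.06 ± 0.25 and 3.30 ± 0.18). Of the 17 members of the MHC class I list 8 were tested and 4 rose (4 adjusted over the list alone, adjusted p = 6.26e-08, and 0.0151 with an estimated correlation). They were B2M (1.07 ± 0.16), NLRC5 (1.69 ± 0.31), an activator of MHC class I genes, PSME1 (0.64) and PSME2 (0.67). PSME1 and PSME2 were chosen after their values were seen.

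NF-kB targets still rose, in smaller number. Of 21 tested 7 were higher (10 adjusted over the list alone, median 0.56), including TNFAIP3 (2.55 ± 0.17), IRF1 (2.36 ± 0.24), NFKB2 (1.85 ± 0.28) and BIRC3 (1.71 ± 0.16). Of 12 cytokines and chemokines 4 rose (7 adjusted over the list alone), with CXCL8 at 1.5 ± 0.16, IL32 at 1.79 ± 0.22, TNFSF10 at 0.93 (chosen after its values were seen) and CCL20 at 2.94 ± 0.919 TPM against 0 listed with zVAD. Of the immediate early genes 1 of 23 rose (3 adjusted over the list alone), ATF3 (1.11 ± 0.25), and its list call was lost with an estimated correlation (adjusted p = 0.196). The iron storage gene FTH1 (0.72 ± 0.13), the laminin gene LAMC2 (1.08 ± 0.10), TGFBI (0.84 ± 0.17), the desaturase gene SCD (0.68 ± 0.08) and the chemokine gene CXCL12 (0.52 ± 0.12) rose, and RET (-0.59 ± 0.11), UBE2C (-0.44 ± 0.10), KRT15 (-0.86 ± 0.17) and the meiotic genes SYCE2 (-0.87 ± 0.17) and DMC1 (-1.17 ± 0.26) fell. So did CYB561D1 (-1.36 ± 0.31), TRIM52-AS1 (-1.24 ± 0.27), LINC01016 (-0.99 ± 0.22), PRTFDC1 (-0.75 ± 0.17), ARHGAP24 (-0.66 ± 0.13), TIMM23B (-0.65 ± 0.15) and CREB3L4 (-0.64 ± 0.14). BIRC2, XIAP, TNFRSF10A, TNFRSF10B, CASP3, CASP8, CFLAR, RIPK1, MLKL and ESR1 did not pass the test (adjusted p from 0.303 to 0.939). MLKL passed as higher with the replicate number as a block (0.0491). No fit with the block on the libraries of this comparison alone was made. Lists that passed with both correlations were NF-kB targets, cytokines, interferon-stimulated genes, MHC class I, the death receptor and IAP list (1 of 26 higher), mesenchymal genes (2 of 11 higher), sterol synthesis (1 of 20 higher), S phase (0 of 21 lower, median -0.27) and G2 and M phase (1 of 22 lower, median -0.24). The adjusted p of these 9 lists with an estimated correlation went from 0.00318 to 0.0337. Lists of p53 targets, stress responses, estrogen-induced genes, NRF2 targets, autophagy and the proteasome passed only at the preset correlation (adjusted p with an estimated correlation 0.251, 0.115, 0.115, 0.359, 0.196 and 0.251). The BCL2 family, heat shock, luminal and hypoxia lists did not pass (adjusted p = 0.494, 0.320, 0.494 and 0.217). In all, 166 genes rose and 25 fell (284 and 162 with GC trends removed). The number was 127 without zVAD 1 and 127 without LCL-161+TRAIL+zVAD 3. The named calls lost in at least 1 alternative were those of ATF3, TGFBI, FTH1, NLRC5, UBE2C, RET, KRT15, SYCE2, IFI6, CXCL12, CYB561D1, TRIM52-AS1, DMC1, LINC01016, PRTFDC1, ARHGAP24, TIMM23B and CREB3L4 (highest adjusted p 0.137, 0.0919, 0.0525, 0.0983, 0.128, 0.0610, 0.0829, 0.0718, 0.0740, 0.173, 0.144, 0.110, 0.139, 0.158, 0.138, 0.0761, 0.148 and 0.172 in that order).

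What zVAD changed in the presence of LCL-161 and TRAIL was tested by LCL-161+TRAIL+zVAD against LCL-161+TRAIL. Immediate early and NF-kB target genes fell. JUN went from 150.4 ± 59.2 to 17.8 ± 2.43 TPM (log2 change -2.93 ± 0.22), JUNB changed by -2.92 ± 0.38, the synaptic immediate early gene ARC by -3.53 ± 0.28, SNAI1 by -3.42 ± 0.25 and HSPA6 by -3.63 ± 0.27. Of 23 immediate early genes 16 fell (19 adjusted over the list alone, median -1.27, adjusted p = 3.59e-23, and 0.00925 with an estimated correlation). Of 21 NF-kB targets 11 fell (19 adjusted over the list alone, median -1.25, adjusted p = 3.20e-20, and 0.0426 with an estimated correlation), ICAM1 from 84.5 ± 37.2 to 8.55 ± 1.78 TPM. The log2 change was -2.38 ± 0.17 for TNFAIP3 and -2.81 ± 0.52 for BCL3, whose values fell into 2 levels within groups. ICAM4 fell to 0.557 ± 0.270 TPM, CCL20 to 2.94 ± 0.919 TPM, CXCL3 to 0.107 ± 0.0822 TPM and CXCL8 to 1.92 ± 0.547 TPM. BBC3 (-2.94 ± 0.44), PMAIP1 (-1.55 ± 0.16), GDF15 (-2.12 ± 0.26), PPP1R15A (-3.09 ± 0.24), HMOX1 (-2.43 ± 0.23), TXNRD1 (-0.94 ± 0.19) and ELF3 (-1.27 ± 0.23) fell as well. ATF3 (-1.89 ± 0.25), HSPA1B (-1.17 ± 0.20), DNAJB1 (-1.02 ± 0.13), STC2 (-0.55 ± 0.13), MYBL1 (-0.54 ± 0.14), ANKRD37 (-0.90 ± 0.16) and RPL11 (-0.30 ± 0.07) also fell. The lists of cytokines, the BCL2 family, p53 targets, stress responses, heat shock, estrogen-induced genes, S phase, G2 and M phase, NRF2 targets and proteasome subunits passed as lower at the preset correlation, but not with an estimated correlation (adjusted p from 0.117 to 0.269). They had 5 of 12, 3 of 14, 5 of 24, 7 of 21, 2 of 14, 6 of 23, 0 of 21, 0 of 22, 4 of 18 and 0 of 26 members lower in that order. Members not covered by the rule, named after their values were seen, were LIF (-1.02), TNFSF9 (-0.73), BCL2 (-0.61), CDKN1A (-1.22), SESN2 (-0.86), CCNG1 (-0.64), GCLM (-0.71) and SRXN1 (-0.36). The death receptor, luminal, mesenchymal, sterol, hypoxia and autophagy lists did not pass (adjusted p = 0.511, 0.579, 0.952, 0.982, 0.579 and 0.644).

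Higher with zVAD in this comparison were 8 of 34 interferon-stimulated genes (19 adjusted over the list alone, median 0.66, adjusted p = 8.27e-12, and 0.159 with an estimated correlation), including XAF1 (1.58 ± 0.34). The MHC class I list passed as higher with 0 of 8 past the threshold (median 0.32, adjusted p = 0.0121, and 0.159 with an estimated correlation). S100A8 rose by 2.27 ± 0.25, ASB9 by 1.39 ± 0.15 and the TRAIL gene TNFSF10 from 1.62 ± 0.455 to 5.04 ± 1.20 TPM. The lysosomal gene HEXB (0.53 ± 0.10) and ZNF18 (1.35 ± 0.34) rose. IFI6 (2.52 ± 0.64) and TRMT2B (1.64 ± 0.29) rose too, and the values of both fell into 2 levels within groups. Mitochondrial protein-coding genes had 10 of 13 higher (median 0.69, and 0.47 after quantile normalization), and small nuclear RNA genes 27 of 53 lower (median -1.0). BIRC3, NFKB2, TNFRSF10B and CFLAR did not pass (log2 changes -0.53, -0.79, -0.31 and -0.31). NFKB2 passed with GC trends removed (adjusted p = 0.0109). CASP3, which MCF-7 cells carry in a form that gives no protein, changed by -0.36 ± 0.10 (adjusted p = 0.0473), a call lost in 20 of 27 alternatives. In all, 212 genes rose and 453 fell (620 and 878 with GC trends removed), 378 in total without LCL-161+TRAIL 4 and 342 on these 8 libraries alone. With mitochondrial genes removed the balance turned to 508 higher and 341 lower. The calls of XAF1, IFI6, CASP3, MYBL1, RPL11, STC2 and ZNF18 reached an adjusted p of 0.117, 0.159, 0.147, 0.0966, 0.142, 0.0986 and 0.159 in other settings.

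All 3 agents together were compared with Control. All 34 tested interferon-stimulated genes rose (median 2.77, adjusted p = 1.69e-88, and 0.00334 with an estimated correlation), with IFIT1 at 5.28 ± 0.38, OAS1 at 4.47 ± 0.26, OAS2 at 4.43 ± 0.31, IFIT3 at 3.88 ± 0.32 and MX1 at 3.84 ± 0.25. NF-kB targets had 7 of 21 higher (9 adjusted over the list alone), including TNFAIP3 (2.80 ± 0.17) and IRF1 (2.11 ± 0.24). Of the 8 MHC class I genes tested, from a list of 17, 4 rose (5 adjusted over the list alone), including B2M (0.99 ± 0.16) and NLRC5 (1.65 ± 0.31). The others were PSME1 (0.46) and PSME2 (0.63), chosen after their values were seen. BIRC3 rose by 1.71 ± 0.16, TRAF3 by 0.83 ± 0.17, CXCL8 by 1.49 ± 0.16, NFKB2 by 1.93 ± 0.28 and LAMC2 by 0.95 ± 0.10. IL32 (1.56 ± 0.22), ATF3 (1.06 ± 0.25), DDIT3 (0.63 ± 0.14), TGFBI (0.95 ± 0.17), FTH1 (0.88 ± 0.13) and SCD (0.48 ± 0.08) rose too, and CCL20 stood at 2.94 TPM. MPP7, whose values fell into 2 levels within groups, changed by -2.21 ± 0.44, MYZAP by -1.79 ± 0.35, MIR6871 by -1.22 ± 0.29, DMC1 by -1.21 ± 0.26 and CAPZA2 by -1.16 ± 0.24. With zVAD alone, CAPZA2 already stood at 7.68 to 23.9 TPM (22.3 to 30.5 in Control) and MIR6871 at 0.152 to 1.10 (1.55 to 2.68). MYZAP stood at 0.149 to 3.43 TPM there (2.70 to 3.94 in Control). DMC1 was not lower with zVAD alone (5.38 to 8.70 TPM), and MPP7 was low only in zVAD 3 (2.83 TPM). None of these differences between zVAD and Control passed the test. Cell cycle genes fell: in S phase 3 of 21 (6 adjusted over the list alone, median -0.36), PCNA (-0.54 ± 0.10), CDC6 (-0.56 ± 0.13) and GINS2 (-0.53), and in G2 and M phase 4 of 22 (12 adjusted over the list alone, median -0.36), CDK1 (-0.70 ± 0.13), UBE2C (-0.58 ± 0.10), CCNB2 (-0.50) and KIF20A (-0.51). GINS2, CCNB2 and KIF20A were chosen after their values were seen. Among estrogen-induced genes 2 of 23 fell (5 adjusted over the list alone, median -0.36), RET (-0.64 ± 0.11) and IGFBP4 (-0.63 ± 0.13). The adjusted p of these 3 lists was 5.36e-09, 1.37e-12 and 1.23e-07, and 0.0170, 0.0170 and 0.0264 with an estimated correlation. NF-kB targets, cytokines (4 of 12 higher), MHC class I, the death receptor list (3 of 26 higher), mesenchymal genes (3 of 11) and sterol synthesis (1 of 20) also passed at both correlations, with TNFSF10 (1.04), MAP3K14 (0.81) and SNAI2 (0.54) among their members named after their values were seen (adjusted p with an estimated correlation from 0.0170 to 0.0372). The p53, stress response, immediate early (1 of 23 higher), autophagy and proteasome lists passed at the preset correlation alone (adjusted p with an estimated correlation 0.184, 0.105, 0.290, 0.111 and 0.152). The BCL2 family, heat shock, luminal, NRF2 and hypoxia lists did not pass (adjusted p = 0.812, 0.106, 0.220, 0.289 and 0.344). BIRC2, XIAP, TNFRSF10A, TNFRSF10B, CASP3, CASP8, CFLAR, RIPK1, MLKL and ESR1 did not pass the test (adjusted p from 0.113 to 0.932). BIRC2 (0.0272) and TNFRSF10B (0.0348) passed with GC trends removed and MLKL (0.0411) with the replicate number as a block. In all, 164 genes rose and 82 fell (323 and 332 with GC trends removed, 211 and 60 with mitochondrial genes removed). The number was 149 without Control 1, 151 without LCL-161+TRAIL+zVAD 3 and 137 without the 2 libraries of the most negative GC trend (Control 3 and LCL-161+TRAIL+zVAD 4), and another split of the 8 libraries, which followed their GC trend, called 1014 genes. The calls of TRAF3, RET, IGFBP4, PCNA, CDK1, CDC6, ATF3, DDIT3, TGFBI, SCD, NLRC5, MPP7, MYZAP, MIR6871, DMC1 and CAPZA2 reached an adjusted p of 0.142, 0.0630, 0.0861, 0.0738, 0.0598, 0.178, 0.189, 0.137, 0.0943, 0.0591, 0.116, 0.114, 0.105, 0.211, 0.114 and 0.12 in that order in other settings.

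**Figure D3:**
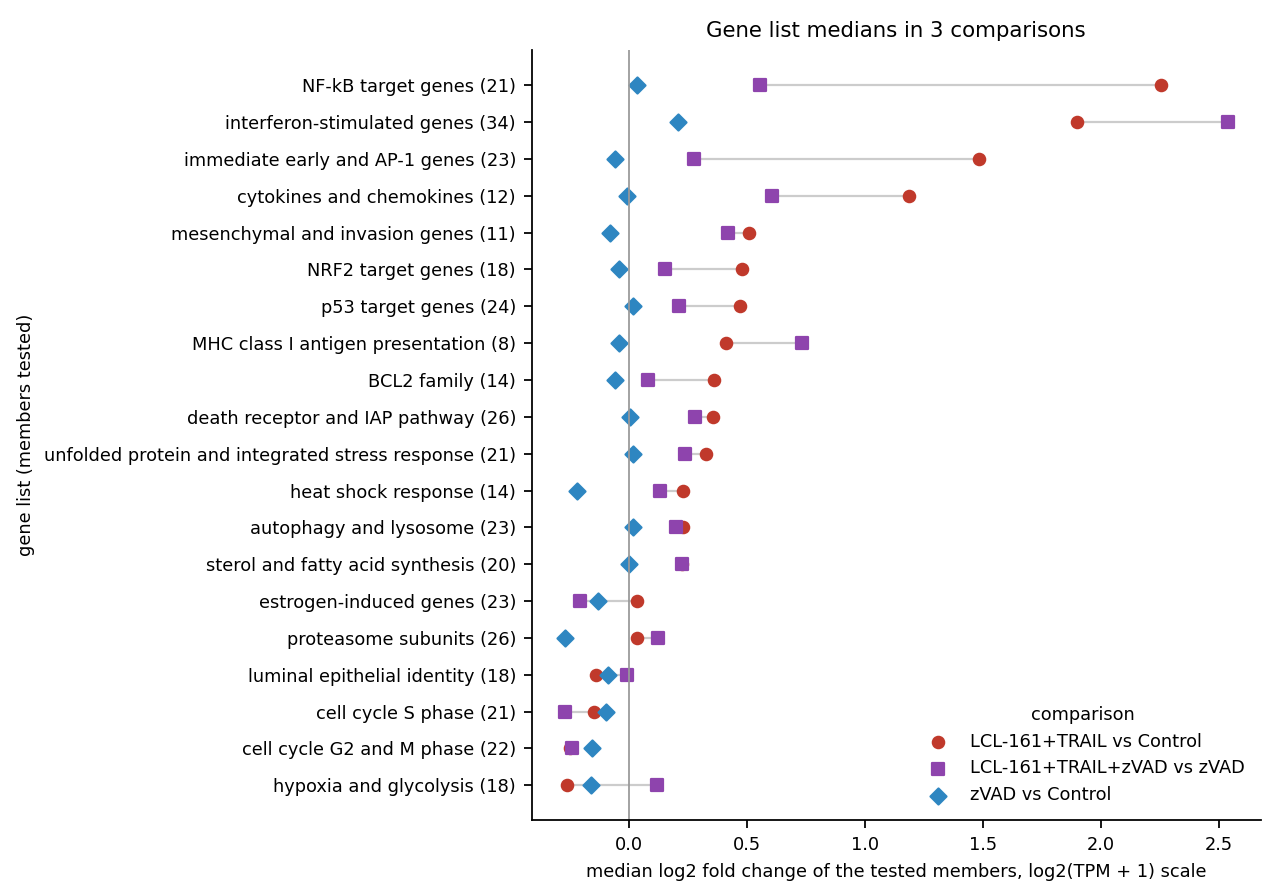
Median log2 fold change (x axis, on the log2(TPM + 1) scale) of the tested members of 20 gene lists (y axis) in LCL-161+TRAIL vs Control (circles), LCL-161+TRAIL+zVAD vs zVAD (squares) and zVAD vs Control (diamonds), with a grey line joining the first pair. The NF-kB median was 2.25 without and 0.56 with zVAD, the immediate early median 1.48 and 0.28, and the interferon median 1.90 and 2.54.

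Whether the effect of LCL-161+TRAIL differed with zVAD was tested directly by the interaction. It was negative for 136 genes and positive for 9 (196 and 36 with GC trends removed). All 136 had risen in LCL-161+TRAIL vs Control, a comparison that shares its libraries with the interaction, and 9 of them also rose in LCL-161+TRAIL+zVAD vs zVAD. ICAM4 (-4.02 ± 0.32), ARC (-3.52 ± 0.40), HSPA6 (-3.46 ± 0.38), PPP1R15A (-3.32 ± 0.34), SNAI1 (-3.30 ± 0.35), ICAM1 (-3.14 ± 0.32), JUN (-2.92 ± 0.31) and NFKBIA (-2.73 ± 0.21) were among them, as was the small nucleolar RNA gene SNORD3A (-3.40 ± 0.23). The interaction was also negative for TNFAIP3 (-2.63 ± 0.25), CXCL8 (-1.85 ± 0.22), GDF15 (-2.18 ± 0.36), PMAIP1 (-1.36 ± 0.23), HMOX1 (-2.49 ± 0.32), BBC3 (-3.07 ± 0.62), JUNB (-2.92 ± 0.53), CXCL3 (-2.57 ± 0.16), CCL20 (-2.32 ± 0.23), ATF3 (-1.83 ± 0.35) and DNAJB1 (-0.93 ± 0.18). It was positive for S100A8 (2.51 ± 0.35), S100A9 (1.85 ± 0.25), ASB9 (1.38 ± 0.21), SPC24 (2.58 ± 0.45) and ANKRD22 (1.10 ± 0.21). SPC24 stood at 62.8 to 86.9 TPM in Control and 19.4 to 25.8 with zVAD alone, a difference that did not pass the test. It stood at 14.6 to 53.1 TPM with LCL-161+TRAIL and 44.0 to 57.4 with all 3 agents.

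By list, 10 of 23 immediate early genes had a negative interaction past the threshold (16 adjusted over the list alone, median -1.34), and 5 of 21 NF-kB targets (13 adjusted over the list alone, median -1.19). Both lists passed at the preset correlation (adjusted p = 1.06e-23 and 1.84e-21) and with an estimated correlation (adjusted p = 0.00842 and 0.0348). CD83 (-2.20), SDC4 (-1.32), CDKN1A (-1.02), ATF4 (-0.89) and DDIT3 (-1.45) had negative interactions past the threshold and were named after their values were seen. Interferon-stimulated genes passed as higher, with a median of 0.46 and 0 of 34 past the threshold in either direction, and the list test at the preset correlation (adjusted p = 9.08e-05) was lost with an estimated correlation (adjusted p = 0.478). Cytokines (3 of 12 negative past the threshold), the BCL2 family (2 of 14), p53 targets (3 of 24), stress responses (4 of 21), NRF2 targets (1 of 18) and estrogen-induced genes (0) passed as lower, and MHC class I (median 0.32), hypoxia (0.25) and the proteasome (0.12) as higher with 0 members past the threshold. All 9 passed at the preset correlation and not with an estimated correlation (adjusted p from 0.146 to 0.478). The death receptor, heat shock (1 of 14), luminal, mesenchymal (1 of 11), S phase, G2 and M phase, sterol and autophagy lists did not pass (adjusted p from 0.235 to 0.932). For BIRC2, BIRC3, XIAP, TNFRSF10A, TNFRSF10B, CASP3, CASP8, CFLAR, RIPK1, MLKL, NFKB2 and ESR1 the interaction was not past the threshold (adjusted p from 0.483 to 0.989). The calls of S100A8, ANKRD22, ATF3, BBC3, DNAJB1 and JUNB were lost in at least 1 other setting (highest adjusted p 0.0957, 0.0631, 0.0667, 0.0620, 0.0623 and 0.0560).

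Across genes, which are not independent replicates, the effects of LCL-161+TRAIL with and without zVAD were compared between groups that share no library. Each ratio below divides by the log2 change on which its genes were selected, which tends to lower it. Of the 1153 genes changed without zVAD, 83.7% (95% interval 81.4 to 85.8) had the same sign with zVAD and 126 passed in both. The median ratio of log2 changes, with zVAD over without, was 0.280. Of the 191 genes changed with zVAD, 96.3% (92.6 to 98.5) had the same sign without it, with a median ratio, here without zVAD over with, of 0.708. For the zVAD effect, 70.1% (66.4 to 73.5) of the 665 genes changed by zVAD under LCL-161+TRAIL had the same sign in zVAD vs Control, with a median ratio of 0.101. Samples of the same number correlated between LCL-161+TRAIL and Control (0.130 to 0.430), and between LCL-161+TRAIL+zVAD and zVAD (0.018 to 0.242). Errors shared in this way favor the same sign even without an effect of zVAD. The share expected from them was not computed, so the 70.1% does not show such an effect.

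**Figure D4:**
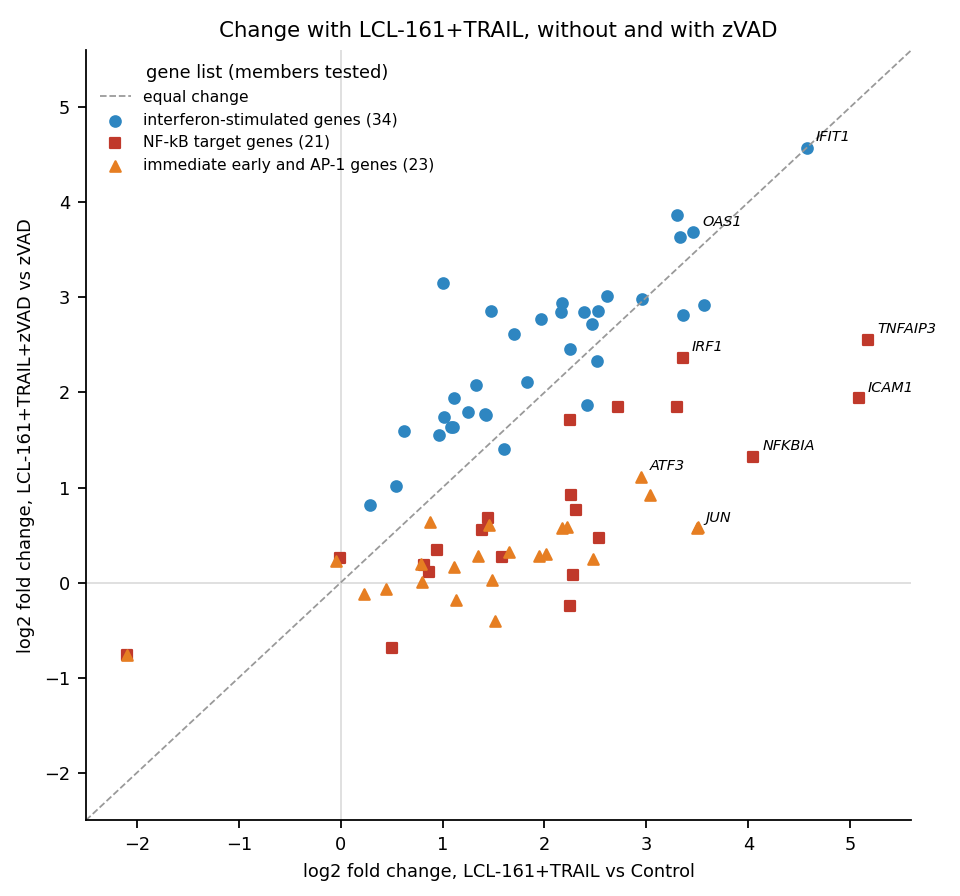
Log2 fold change of the tested members of 3 lists in LCL-161+TRAIL vs Control (x axis) and in LCL-161+TRAIL+zVAD vs zVAD (y axis), a point per gene, with a dashed line where both are equal; a gene in more than a single list is drawn for each. TNFAIP3 lies at 5.18 and 2.55 and JUN at 3.49 and 0.57, below the line, and IFIT1 lies at 4.57 and 4.57, near it.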

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

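Tests chosen only after the result was seen were the difference between interferon-stimulated genes and NF-kB or immediate early genes, the overlap of genes in its final form with RefSeq synonyms, the splits repeated after the GC correction, read by pairs or, for the interaction, taken on residuals, and values with the replicate block after the GC correction. In 462 groups of 4 libraries, 24 had a library far from the other 3, by a gap to the nearest library, divided by the range of the group, above Dixon's 95% critical value, where chance gives about 5% of groups. The libraries were spread over 11 of the 16, with at most 3 each. The gap took the whole range (1) for CXCL8 in Control 1 and in zVAD 3 and for IFNL2 in zVAD 3, where the other 3 libraries were listed at 0. It was 0.895 for ANKRD37 and 0.920 for MYZAP in Control 1, 0.868 for ZNF18 in Control 2, 0.886 for NFKB2 in zVAD 1, 0.858 for ASB9 and 0.868 for CDK1 in zVAD 2, 0.980 for MPP7 in zVAD 3, and 0.855 for DDIT3, 0.907 for PARP9 and 0.994 for the GC slope in zVAD 4. In LCL-161+TRAIL 4 it was 0.901 for CCL20, 0.894 for FTH1 and 0.881 for XAF1. With all 3 agents it was 0.841 for BIRC3 and 0.892 for MT-ND6 in library 1, 0.830 for NFKBIA, 0.920 for NLRC5 and 0.874 for OAS1 in library 2, 0.845 for SCD and 0.865 for VEGFA in library 3, and 0.916 for ELF3 in library 4.

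The effect of LCL-161+TRAIL differed with and without zVAD, by the interaction test, for 27 of the named genes. The difference in log2 change was -4.02 for ICAM4, -3.52 for ARC, -3.46 for HSPA6, -3.40 for SNORD3A, -3.32 for PPP1R15A, -3.30 for SNAI1, -3.14 for ICAM1, -3.07 for BBC3, -2.92 for JUNB, -2.92 for JUN, -2.73 for NFKBIA, -2.63 for TNFAIP3, -2.57 for CXCL3, -2.5 for RASD1, -2.49 for HMOX1, -2.32 for CCL20, -2.18 for GDF15, -1.85 for CXCL8, -1.83 for ATF3, -1.45 for DDIT3, -1.36 for PMAIP1 and -0.93 for DNAJB1. It was positive for SPC24 (2.58), S100A8 (2.51), S100A9 (1.85), ASB9 (1.38) and ANKRD22 (1.10). For SPC24 the values with zVAD alone (19.4 to 25.8 TPM) lay below those of Control (62.8 to 86.9), without passing the test.

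Among genes too low on average to be tested, 12 reached 2 TPM on average in a treated group and stood far lower in Control. With LCL-161+TRAIL these were NEURL3 (3.23 TPM), RN7SKP150 (2.89), RNA5SP226 (2.86), RNA5SP389 (2.78), APOE (2.59), STX11 (2.51), C11orf96 (2.38), DIO3 (2.37), KRT17 (2.37) and TMEM156 (2.01). With all 3 agents they were TMEM140 (2.23) and TRIM22 (2.09). The highest of their means in Control was 0.442 TPM (STX11), and no test was made.

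The first pattern was the set of 136 genes whose rise with LCL-161+TRAIL was smaller under zVAD. After each library lost its GC trend, 93.2% (110 of the 118 with a GC value) were still past the threshold in the same direction, with a median of -1.62 against -1.66 before. With mitochondrial genes removed, 94.0% (126 of the 134 that could be tested) were, so neither trend was the whole cause. A weaker effect on all responding genes alike was argued against by the genes that had risen with LCL-161+TRAIL. Among these, 28 interferon-stimulated genes had a median interaction of 0.35 and 34 NF-kB or immediate early genes had -1.50, a difference of 1.85 (permutation over genes, p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates, so this p overstates the evidence. All 34 NF-kB or immediate early genes and 6 of the 28 interferon-stimulated genes had a negative interaction. The medians had been alike without zVAD, 2.21 for the interferon-stimulated genes and 2.23 for the others. Inhibition of caspases itself, a shift in timing or in the number of dying cells, and effects of zVAD on other proteases were not tested and stay open, and the treatment time is not given.

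The second pattern was the rise of several RNA classes without a poly(A) tail, or with short tails at most, in LCL-161+TRAIL. After the GC correction the small nuclear RNA median was 98.0% of its value (0.98 against 1.00), which argues against GC bias, and with the replicate block it was 0.98 after the correction too (1.00 before). Each LCL-161+TRAIL library had a class median above each Control library for small nuclear, histone, mitochondrial ribosomal and small nucleolar RNA, but not for small Cajal body RNA (3 genes) or microRNA. This is the pattern itself and decides nothing about its cause. For mitochondrial ribosomal RNA it was not particular to LCL-161+TRAIL. Each library with zVAD (13.95 to 14.16) or all 3 agents (13.90 to 13.93) was also above each Control library (13.35 to 13.71). Small nucleolar RNA medians with all 3 agents (1.65 to 2.02) were above those of Control (1.37 to 1.63) as well. A smaller yield of polyadenylated RNA was tested on 6 other RNAs without a poly(A) tail (RN7SK, RN7SL1, RN7SL2, RNY1, VTRNA1-2 and VTRNA1-3). The difference of their medians per library was 0.40 (95% interval -0.12 to 0.92), with library medians of 2.64 to 3.33 in LCL-161+TRAIL and 2.32 to 2.90 in Control. Of the 6, RN7SK (log2 change 1.70, adjusted p = 0.0157) and RNY1 (1.54, 0.0253) passed the threshold as higher, by more than the small nuclear RNA median, while VTRNA1-2 (0.66), RN7SL2 (0.20), RN7SL1 (0) and VTRNA1-3 (-0.27) did not pass. The 6 did not move alike and the library medians overlap, so this explanation cannot be told apart from others, whether through handling of the RNA or a loss of messenger RNA in dying cells. TPM hold no absolute amounts that would separate the 2. Imprecise values of very short genes cannot be told apart from the pattern, since the small nucleolar RNA median was 51.0% of the small nuclear RNA median and the microRNA median 8.53%, on either side of the 50% set beforehand.

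The third pattern was 274 tested genes (1.83%) whose values fell into 2 levels within a group, of which 19 passed the threshold in any comparison, and RAB5B, IFI6, TRMT2B, BCL3 and MPP7 are among the named genes. An explanation is that reads of overlapping genes on the same strand were given to either gene. Of the 220 with a known position, 94 (42.7%) overlapped another gene on the same strand, against 4354 of 12859 other tested genes (33.9%), an odds ratio of 1.46 (95% interval 1.10 to 1.92, Fisher p = 0.00776). The first matching placed 215 of the 274 (78.5%), under the 80% needed, so that test was void. Its result (Fisher exact test, odds ratio 1.46, interval 1.10 to 1.93, p = 0.00722, 92 of 215 against 4274 of 12603) had been seen before RefSeq synonyms raised the share to 80.3%. Because the wider matching was chosen after the result, and the authors' annotation is unknown, the explanation cannot be told apart from others. No biological explanation was tested for this pattern.

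Other splits of the libraries into 4 and 4 tested whether chance can be excluded, with fits on the 8 libraries of each comparison. For LCL-161+TRAIL vs Control, 1 of 35 splits, the real split, gave as many genes (507, highest other 14). Of the 8 splits that part all 4 pairs of the same number, as the real one does, the highest other gave 2, and the 14 came from a split that parts fewer. For LCL-161+TRAIL+zVAD vs zVAD, 1 of 35 did (123, highest other 5), and for LCL-161+TRAIL+zVAD vs LCL-161+TRAIL, 1 of 35 (342, highest other 10). Where any of the 35 splits is taken as possible, chance is unlikely for these 3, at 1 of 35, the smallest share that these splits can give. The other splits mix libraries of both groups on each side. Any effect then adds to the spread and lowers their counts, so the highest other is no measure of chance. Read by pairs, as the numbers were taken for LCL-161+TRAIL vs Control, the smallest share is 1 of 8. That is too few splits to exclude chance for this comparison. For zVAD vs Control, 8 of 35 splits gave at least as many genes (3, highest other 5), and chance is not excluded. For LCL-161+TRAIL+zVAD vs Control, 2 of 35 did, and chance is not excluded: the real split gave 122 genes and another gave 1014, which points to a structure of the samples. That split set Control 1 and 3 with LCL-161+TRAIL+zVAD 2 and 4 (GC slopes -0.34 to -0.04) against the other 4 (0.10 to 0.19). After the GC correction the real split gave 369 genes, the highest other 12, and 1 of 35 splits gave as many. For the interaction, plain splits carry the effect of LCL-161+TRAIL into the groups, so 100 splits of the 16 libraries were taken on the values left by a fit of the separate effects. Of these, 2 gave at least as many genes (145, highest other 1066). Chance is not excluded by this count, since the 1066 points to a structure of the samples. After the GC correction 1 of the 100, the real one, gave as many (232, highest other 99). That makes chance unlikely on the corrected values, in a check chosen after the result was seen.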

How the results depend on the processing

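Alternatives chosen after seeing the data were the removal of GC trends, of mitochondrial genes, of genes with 2 levels and of the 2 libraries with the most negative GC trends (Control 3 and LCL-161+TRAIL+zVAD 4), and 2 fits with a block. Comparisons are given as LCL-161+TRAIL vs Control, LCL-161+TRAIL+zVAD vs zVAD, LCL-161+TRAIL+zVAD vs LCL-161+TRAIL, LCL-161+TRAIL+zVAD vs Control and the interaction, in that order, where numbers follow each other; the counts reported were 1153, 191, 665, 246 and 145 genes. No named gene or list changed direction while past the threshold in any alternative. Counts stayed within 1.5 times for these 5 comparisons without the trend, after quantile normalization, with no filter, with a pseudocount of 0.1, without mitochondrial genes and without genes of 2 levels (LCL-161+TRAIL vs Control 1139 to 1344, interaction 128 to 211).

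With a mean of at least 5 TPM, which tests 10450 genes, the counts were 740, 113, 403, 159 and 78, and all of these had been called before. At an adjusted p below 0.01 they were 494, 111, 296, 125 and 81, as a stricter threshold gives. Fitted on only the libraries of the groups compared, which leaves fewer samples, the first 4 were 507, 123, 342 and 122. With GC trends removed, among 13080 genes, they were 1944, 446, 1498, 655 and 232, of which 952, 179, 547, 223 and 119 had been called before in the same direction; the cause of the added calls was not tested. The share of changed genes that rose then went from 86.9 to 63.7% for LCL-161+TRAIL+zVAD vs zVAD, from 66.7 to 49.3% for LCL-161+TRAIL+zVAD vs Control and from 6.21 to 15.5% for the interaction. Without mitochondrial genes it went from 31.9 to 59.8% for LCL-161+TRAIL+zVAD vs LCL-161+TRAIL and from 66.7 to 77.9% for LCL-161+TRAIL+zVAD vs Control, so these balances depend on the processing. Without the 2 libraries of most negative GC trend, LCL-161+TRAIL+zVAD vs Control gave 137. For zVAD vs Control (0 genes) there were 2 genes with no filter, 3 on its own libraries and 1 without the 2 libraries, and 0 in the other alternatives that kept all libraries; the cause was not tested.

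Leaving out each library in turn gave 566 (without LCL-161+TRAIL 4) to 1215 genes for LCL-161+TRAIL vs Control, with 717 without Control 1; 0 to 3 for zVAD vs Control, with 3 without Control 2 or zVAD 3 and 1 without Control 3 or zVAD 4; and 127 (without zVAD 1 or LCL-161+TRAIL+zVAD 3) to 188 for LCL-161+TRAIL+zVAD vs zVAD. It gave 378 (without LCL-161+TRAIL 4) to 701 for LCL-161+TRAIL+zVAD vs LCL-161+TRAIL, 149 (without Control 1, with 151 without LCL-161+TRAIL+zVAD 3) to 270 for LCL-161+TRAIL+zVAD vs Control, and 104 to 163 for the interaction.

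With the replicate number as a block, LCL-161+TRAIL vs Control, where the numbers paired the samples, gave 1613 genes (1269 on its own 8 libraries, against 507 without the block, and 2434 after removal of GC trends, against 1944). The 4-group block changed no list call there but that of heat shock, and no named call but those of TNFRSF10A, CFLAR, RIPK1 and DNAAF3. On the 8 libraries 8 named calls were lost and 1 gained, and after removal of GC trends 0 were lost and 5 gained (TNFRSF10A, CFLAR, RIPK1, BIRC2 and CASP3). There, 2 of 12 pairs of other numbers also correlated above 0.1, and 6 of 8 libraries were closest to their own number (8 with GC trends removed). Between LCL-161+TRAIL+zVAD and zVAD, 3 of the 4 pairs of the same number correlated above 0.1, against 0 of 12 other pairs. Of these libraries 6 of 8 were closest to their own number (8 with GC trends removed). This hints at pairing there too, from the data and not the design, and is not settled. Of the 4 pairs, 1 correlated above 0.1 between zVAD and Control and 0 in the other comparisons. With the block these gave 264, 0, 1036 (LCL-161+TRAIL+zVAD vs LCL-161+TRAIL) and 404 genes (LCL-161+TRAIL+zVAD vs Control), and the interaction 154; the cause was not tested.

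With an estimated correlation, 6, 9, 2, 10 and 2 lists passed where 15, 16, 14, 15 and 12 had, and for zVAD vs Control 0 passed where 7 had. Such a correlation widens the null, and 50 of 79 list calls were lost. With fry, 1 list passed for zVAD vs Control and 5 for the interaction; the cause was not tested. Leaving out a library gave 4 (without Control 2) to 7 lists for zVAD vs Control, 13 to 16 for LCL-161+TRAIL vs Control, 15 to 17, 13 to 14, 14 to 15 and 9 to 12 for the other comparisons in order. In all, 14 list calls were lost and 2 gained when some library was left out. The S phase call in LCL-161+TRAIL vs Control was lost without Control 4 (adjusted p = 0.131), LCL-161+TRAIL 3 (0.0602) or 4 (0.126), or LCL-161+TRAIL+zVAD 3 (0.0507), and the MHC class I call there without Control 2 (0.0667), LCL-161+TRAIL 2 (0.0733), or LCL-161+TRAIL+zVAD 1 (0.0580) or 3 (0.0508).

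Of 251 pairs of a named gene and a comparison, 185 were past the threshold and 120 of these stayed so in every alternative in which they were tested. The adjusted p below 0.01 was not applied to named genes, here or in the lost calls listed above. At a mean of at least 5 TPM only 210 pairs could be tested. Calls were lost for 45 pairs when some library was left out, 45 on own libraries, 37 without the 2 libraries, 18 with no filter and 8 or fewer in each other alternative. The same-sign share of LCL-161+TRAIL effects with and without zVAD, 83.7%, was 87.7% at an adjusted p below 0.01 and 80.6 to 86.6% when a library was left out. The share for genes changed under zVAD, 96.3%, was 95.5 to 97.7%. That for the zVAD effect, 70.1%, was 65.9% at an adjusted p below 0.01 and 65.5 to 72.9%. Depth is unknown from TPM, so what it limits could not be computed.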

Other observations

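Few genes carried by other cell types were above the filter. Of the marker lists, 2 of 8 fibroblast genes, 0 of 8 leukocyte genes, 0 of 6 endothelial genes and 1 of 7 basal or myoepithelial genes reached a mean of 1 TPM, and 0 of these 3 passed limma's test in any of the 6 comparisons over all genes. KRT17, a basal marker below the filter and so not tested, averaged 0.140 TPM in Control and 2.37 with LCL-161+TRAIL. It averaged 0.107 TPM with zVAD and 0.473 with all 3 agents. Ribosomal protein genes took 13.1 ± 0.783% of the TPM in Control, 15.2 ± 0.951% with LCL-161+TRAIL, 12.2 ± 0.627% with zVAD and 12.7 ± 0.338% with all 3 agents (mean ± SD, n = 4). The 10 most abundant genes took 15.9, 13.4, 20.2 and 18.2% in the same order. In the table, 25380 gene entries were listed at 0 in all 16 libraries. The first principal component held 21.5% of the variance.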
